A study of Mus musculus with 21 samples.

How the data were processed

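The series held 21 samples from the basal ganglia primordia (ganglionic eminences) of mouse embryos of the CD1 strain. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done at embryonic day 13.5 with antibodies to 6 subunits of NuRD, a chromatin remodelling and histone deacetylase complex, with 1 library per subunit and 3 input libraries. Per the labels' protocols, cells were fixed with 5 mM DSG and then 1% PFA, nuclear extracts were sonicated for 10 minutes, and libraries were size selected at 180 to 400 bp. The labels pair CHD4 and MBD3 with input 2, HDAC1 and HDAC2 with input 1, and RBBP4 and RBBP7 with input 3, so some of the overlap between lists that share an input may come from that input. Chromatin accessibility (ATAC-seq) was measured at embryonic day 12.5 in wild-type (WT) and Dlx1/2 knockout (KO) embryos. Cells were separated into FTpos cells of the ventricular zone (VZ) and FTneg cells of the subventricular and mantle zones, with 3 embryos per genotype and fraction. The sample titles number the embryos of each genotype 1 to 3 in both fractions. The 2 fractions thus appear to come from the same embryos and are not independent of each other. A protocol specific to ATAC-seq was not given in the sources used here.

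Per the submitters' processing notes, the tools were BWA, SAMtools 1.10, MACS2 2.2.7.1, Genrich and deepTools, and the build was mm10. Tool settings were not given in the sources used here. Each ChIP library came as 1 deposited list of peaks called against input, from which blacklisted regions had been removed per the names of the lists. The value of each ChIP peak is the fold enrichment at its summit, a ratio that the authors' caller computed. The same deposited lists give the −log10 p and −log10 q of each peak, also from the authors' caller. The accessibility data came as 4 deposited lists, 1 per genotype and fraction, each called by comparing 1 genotype with the other over the embryos together. The score of each accessibility region is the area under the curve of −log10 p over the region as deposited by the authors, who kept regions with an area of at least 500. All fold enrichments, −log10 values and areas per peak are the authors' values and were used to describe, rank or filter peaks within a list. The exceptions are the alternative without technical regions, in which a position with an extreme summit value in 1 accessibility list was left out of all 4, and 1 comparison of areas over the 4 accessibility lists together, given with the values within each list. The direction of each accessibility list was taken from the labels, which attach it to the samples of the genotype that its name puts first.

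For 3 of the 6 ChIP samples the labelled subunit and the name carried by the attached list differ. The list attached to the CHD4 sample carries the name HDAC1, that of the HDAC1 sample carries HDAC2, and that of the HDAC2 sample carries CHD4. The MBD3, RBBP4 and RBBP7 lists carry their own names. Lists are named here by the sample label, and which name is right could not be settled from the files.

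Read counts and depths were not used here, so the depth behind each list is unknown. With 1 list per ChIP target, and with the embryos combined in each accessibility list, no list has a replicate. The tests below compare lists of regions, which are not independent replicates, and not embryos. Wilson 95% intervals on shares cover counting error over regions only.

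Lists were compared by overlap of at least 1 bp. Chance overlap came from 1000 circular shifts of 1 list within each chromosome (one-sided permutation p, smallest possible value 0.001). For regions shared by all 6 lists, every list was shifted independently in 100 sets (smallest possible p 0.0099). Shares were compared by two-sided Fisher's exact tests, with 0.5 added to each cell of an odds ratio where a cell was 0. Shifts and gene-based results covered chromosomes 1 to 19 and X. Benjamini-Hochberg adjustment was made over the 15 pairs of ChIP lists, over the 36 overlaps of accessibility and ChIP lists, over the 18 contrasts of KO-higher and WT-higher overlap, and over the 44 tests of gene lists near accessibility regions.

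Genes were those of the RefSeq annotation of GRCm38.p6, the assembly of mm10. The table used gives the start and end of each gene but neither strand nor exons, and no genome sequence was used. The planned window around transcription start sites was therefore replaced by gene ends, within 1 kb of either annotated end of a protein-coding gene with a curated transcript (21031 of 21887 protein-coding genes). That filter was chosen after the files had been opened. Regions were assigned to the nearest such gene body by their summit, and introns could not be told from exons. A planned comparison of homeodomain motifs needed the genome and was not run. For each of 11 gene lists fixed before the data were examined, the number of regions nearest to a member was tested with a one-sided exact binomial test against the share of 1 kb genome bins nearest to its members. The lists were NuRD subunits, ventricular zone progenitor, GABAergic lineage, Notch pathway, cortical glutamatergic, oligodendrocyte and astrocyte, cholinergic, endothelial and mural, microglial, cell cycle and housekeeping genes. All 173 distinct genes of the lists matched the annotation.

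Named genes followed a rule also fixed before the data were examined. It took the genes nearest to the 10 regions of highest area in each accessibility list (20 for KO-higher FTneg), genes with 3 or more regions of 1 list, and members of a fixed list with a region. It also took the 10 regions of all 6 ChIP lists with the best worst rank of fold enrichment, and members of a fixed list whose gene ends held all 6 lists or none. Some genes that the rule takes are not reported here.

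On simulated data, shares of 0, 2, 10 and 50% planted among 727 regions were estimated as -0.00279, 2.65, 8.97 and 49.9%. Of 40 sets of unrelated regions 5% gave p below 0.05. Simulated regions and peaks lay at random positions along the chromosomes. This rate therefore does not cover lists that cluster together in open chromatin. All 300 planted regions of 6 lists were found, and 1 gene list passed with 40 planted regions and 0 without. Alternatives tried were stricter peak thresholds, lists of equal length (5517 peaks), summits within 250 bp, coverage of at least 50% of a region, shifts of 50 to 500 kb, gene end windows of 500 and 2500 bp, an area of at least 1000, joining of regions under 1 kb apart, autosomes only, other backgrounds for the gene lists, and removal of single lists. Technical regions, left out in a further alternative chosen after the data were seen, were those within 50 kb of Dlx1 and Dlx2 or at positions where any accessibility list had a summit −log10 p of at least 20. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.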

Results

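The data comprised 6 lists of NuRD subunit peaks from embryonic mouse ganglionic eminences and 4 lists of regions whose accessibility differed between WT and Dlx1/2 KO embryos (3 embryos per genotype and fraction, combined in each list). DLX1 and DLX2 are homeodomain transcription factors of the GABAergic lineage of the ventral forebrain. The comparisons asked where the subunits of NuRD were found together and where chromatin was more or less open without DLX1 and DLX2. They also asked whether the latter places overlapped peaks of NuRD subunits. The ChIP lists held 91480 peaks in total and the accessibility lists held 727 KO-higher and 53 WT-higher regions in FTneg and 12 and 33 in FTpos. There were no replicates for any list, and the depth of each library is unknown. For 3 ChIP samples the list carries another subunit's name (HDAC1 for the CHD4 sample, HDAC2 for HDAC1 and CHD4 for HDAC2), so statements on these 3 subunits hold for the list labelled so and not necessarily for the protein.

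The 6 subunit lists differed in length and in how often they lay at genes. RBBP4, a histone-binding subunit, had the most peaks (29762) and the list labelled HDAC2 the fewest (5517). The CHD4-labelled list held 18274 peaks, RBBP7 14918, MBD3 11721 and the HDAC1-labelled list 11288. Peaks lay at gene ends most often in the CHD4-labelled list (57.7%, 95% interval 57.0 to 58.5) and least often in RBBP7 (17.8%, 17.1 to 18.4). The HDAC1-labelled list had 55.9% of its peaks there, MBD3 43.4%, the HDAC2-labelled list 37.3% and RBBP4 36.0%. Median fold enrichment per list, by the authors' caller, ran from 4.21 for the HDAC2-labelled list to 6.20 for RBBP7, and median peak width from 412 to 635 bp.

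The subunits occurred at the same places far more often than shifted lists did. Of MBD3 peaks, 92.3% (91.8 to 92.7) overlapped an RBBP4 peak, against 1.48% after shifts. Of RBBP7 peaks, 65.5% overlapped RBBP4 (1.43% after shifts), and of MBD3 peaks 41.9% overlapped RBBP7 (0.648%). These 3 lists carry the names of their samples. Over the 15 pairs the median log2 ratio of observed to shifted overlap was 6.0, a value that does not depend on the naming of the lists, and every pair had an adjusted permutation p of 0.001, the smallest the shifts can give. The ratio was highest for the HDAC2-labelled list with MBD3 (log2 7.05, 66.3% against 0.499%) and lowest for RBBP7 with the CHD4-labelled list (log2 5.07, 33.1% against 0.982%). Shifts do not keep peaks in open chromatin, so the ratios measure overlap against arbitrary positions and not against accessible ones.

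**Figure D1:**
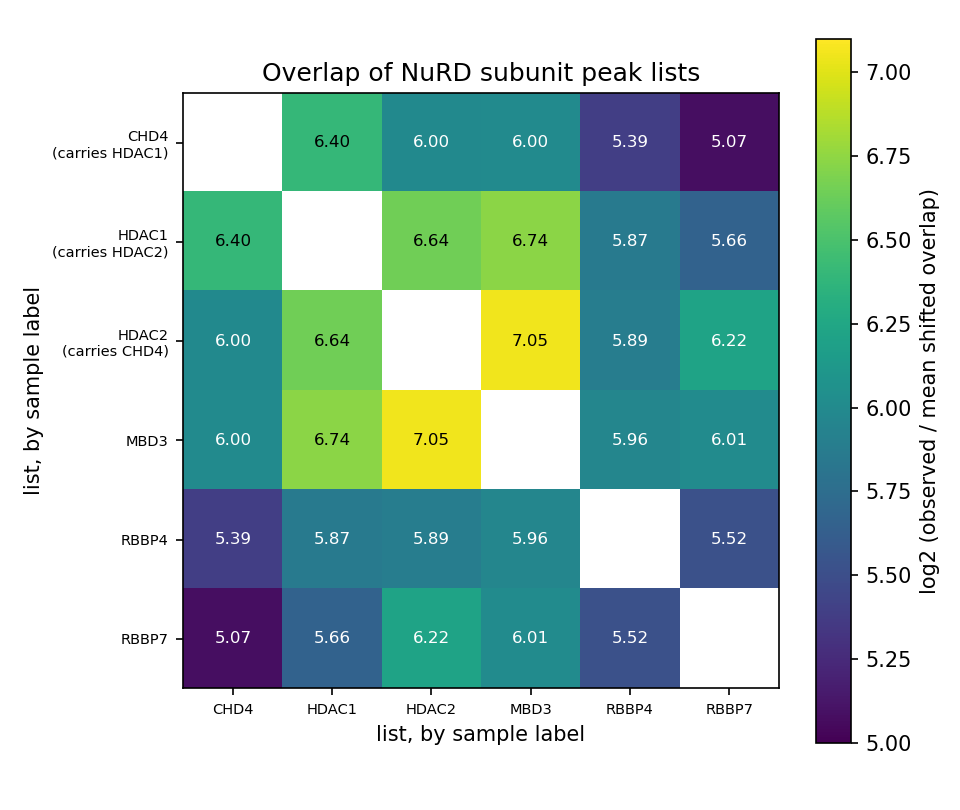
Log2 ratio of observed to mean shifted overlap for each pair of the 6 lists (colour and number in each cell, no unit), with lists named by sample label and the differing carried name in brackets. Values run from 5.07 (RBBP7 with the CHD4-labelled list) to 7.05 (the HDAC2-labelled list with MBD3).

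Merging the 6 lists gave 38820 regions, of which 1527 (3.93%) held a peak of every list. No region of 6 lists arose in any of 100 sets of shifted lists (permutation p = 0.0099, the smallest they can give). The region with the best worst rank lay within Cacng4, which encodes an auxiliary subunit of AMPA receptors (chromosome 11, 107783686 to 107784798), with fold enrichments of 16.0 in the HDAC2-labelled list to 50.7 in RBBP7. A second region within Cacng4 (107785009 to 107786501) ranked next after it and Acvr1b. Acvr1b, an activin receptor gene, held 1 (chromosome 15, 101196044 to 101197258), as did the calpain gene Capn2 (chromosome 1, 182500698 to 182501562). The remaining 6 of the 10 lay within Cradd, BC052040 and Gfra1, a receptor for the growth factor GDNF, or had Ifngr1, Fam110b and the corepressor gene Tle4 as the nearest genes at 77462, 161640 and 179232 bp. None of these 10 regions lay at a gene end. The number of shared regions depended on the peaks admitted: 219 remained at a −log10 q of at least 10, and 2706 regions held the other 5 lists when the short HDAC2-labelled list was left out.

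Gene ends made up 40.9% (38.4 to 43.4) of the regions of all 6 lists and 21.6% (21.0 to 22.2) of those of 1 list (odds ratio 2.51, Fisher's exact p = 1.26e-58). In between, the share was 35.1% with 2 lists, 49.8% with 3, 55.5% with 4 and 55.4% with 5. The direction of the contrast between 6 lists and 1 was not stable. With peaks of a −log10 q of at least 10 the odds ratio was 0.621 (Fisher's exact p = 0.00213), and with lists of equal length or summits within 250 bp it was 0.761 and 0.923.

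Of 20953 genes, 628 (3.0%) had all 6 lists at their ends and 8942 (42.7%) had none. Each list was counted at either end of a gene, so the peaks of the 6 lists need not overlap or share 1 end. All 6 lists were found at 3 of 15 NuRD subunit genes (Hdac2, Mbd2 and Mbd3), at 3 of 17 Notch pathway genes (Dll1, Hes6 and Jag1) and at 4 of 38 GABAergic lineage genes (Foxp2, Meis1, Sox11 and Tshz1). They were also found at the ventricular zone progenitor genes Fabp7 and Vax1 (2 of 22) and the cortical glutamatergic genes Fezf2 and Neurod1 (2 of 16). None of the 11 gene lists passed Fisher's exact test after adjustment, and 3 had an unadjusted exact p below 0.05 (0.00932 for NuRD subunits, 0.0133 for Notch and 0.0264 for GABAergic lineage genes). The odds ratio and adjusted p of this exact test were 8.13 and 0.0732 for NuRD subunits, 6.96 and 0.0732 for Notch and 3.83 and 0.0967 for GABAergic lineage genes, and the adjusted p was 0.224 for cortical glutamatergic and 0.308 for progenitor genes. No oligodendrocyte and astrocyte, cholinergic, endothelial and mural, microglial, cell cycle or housekeeping gene held all 6 (Fisher's exact test, adjusted p = 1 each).

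The share of genes without a peak at their ends, 42.7% over all genes, varied between the gene lists, and these shares were not tested. Of the microglial genes 6 of 8 had none (Aif1, C1qb, Csf1r, Cx3cr1, Spi1 and Tyrobp), and of the endothelial and mural genes 9 of 14 (Cdh5, Col1a1, Col1a2, Dcn, Pdgfrb, Pecam1, Rgs5, Tek and Tie1). Of the oligodendrocyte and astrocyte genes 6 of 13 had none (46.2%, close to the share over all genes, among them Aldh1l1, Aqp4, Cspg4, Gfap and S100b). None of the 15 NuRD subunit genes, 22 progenitor genes or 10 housekeeping genes lacked a peak, and of 38 GABAergic genes Zfhx3 alone did. The Notch genes Heyl and Rbpj, the glutamatergic gene Nhlh1, the cholinergic gene Slc5a7 and the cell cycle inhibitor Cdkn1a also had none.

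**Figure D2:**
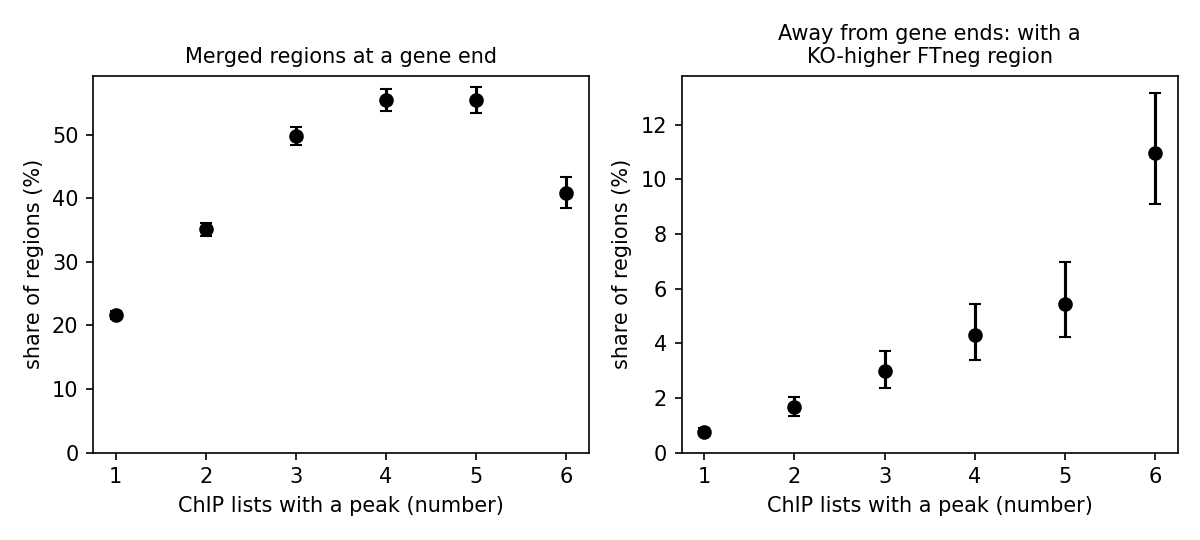
Share of merged ChIP regions (%, points, with Wilson 95% intervals as bars) by the number of lists with a peak, for regions at a gene end (left) and, among regions away from gene ends, for those that overlap a KO-higher FTneg region (right). The share at gene ends is 21.6% with 1 list and 40.9% with 6, with a maximum of 55.5% at 4, and the share with a KO-higher region is 0.758% with 1 list and 11.0% with 6.

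The targeted locus was checked first. In FTneg cells the 5 regions of highest area in the WT-higher list lay at Dlx1 and Dlx2, with areas of 3264 to 21511. They covered 90.3% of the 15.5 kb from 71530506 to 71546030 on chromosome 2, from within Dlx1 (71528113 to 71533981) to within Dlx2 (71543408 to 71546754). The WT-higher FTpos list had 5 regions nearest to Dlx1 or Dlx2, from 71530499 to 71546125. In both fractions the regions lay over the gene bodies and over the interval between them.

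**Figure D3:**
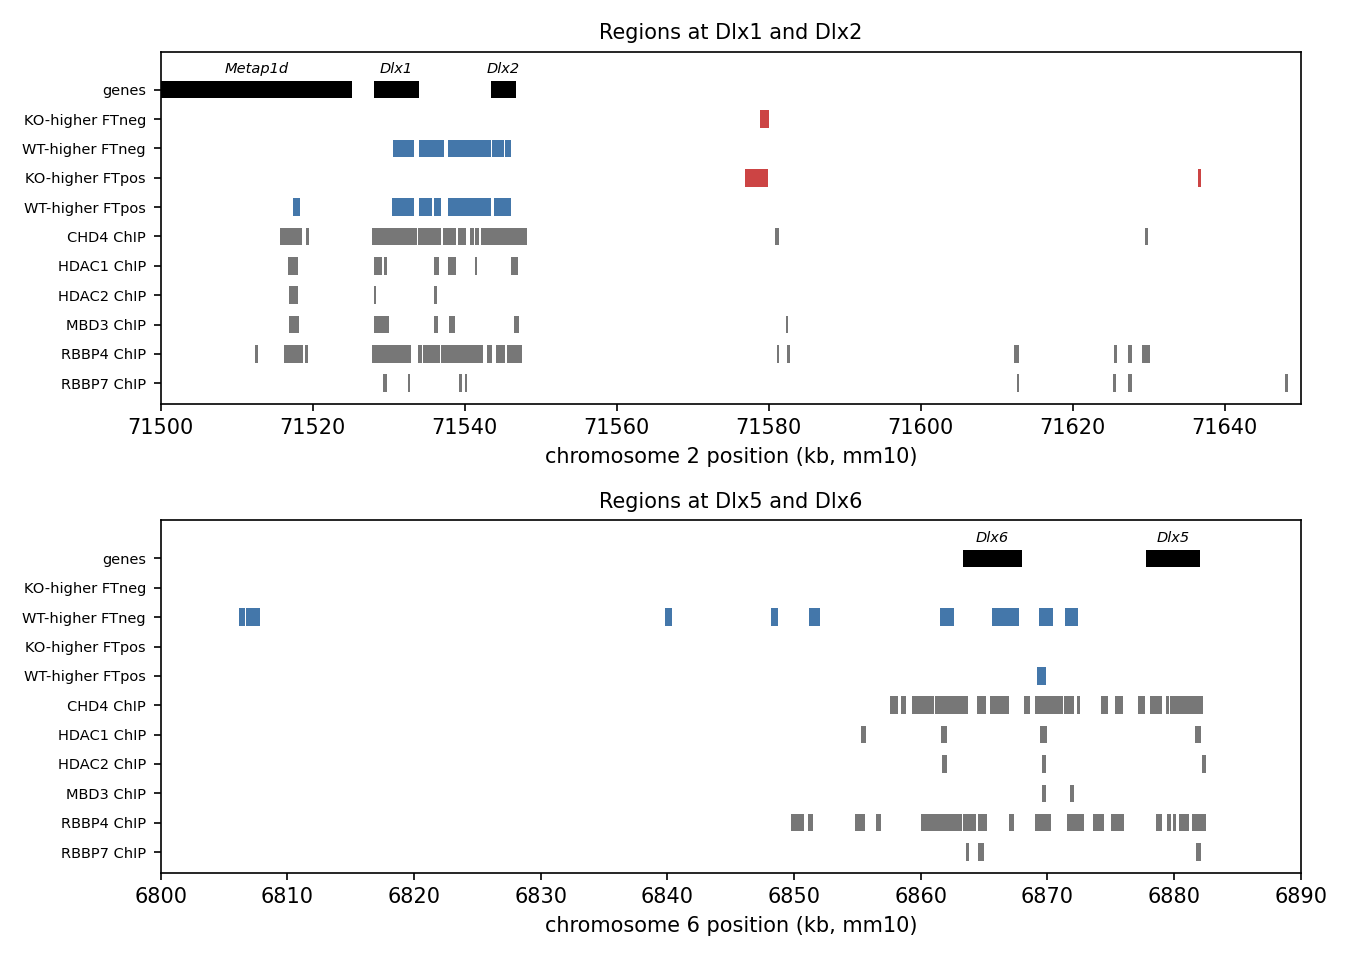
Regions of the 4 accessibility lists and the 6 ChIP lists (1 track each, bars to scale) with genes in black along chromosome 2 at Dlx1 and Dlx2 (top) and chromosome 6 at Dlx5 and Dlx6 (bottom), positions in kb of mm10. WT-higher FTneg regions cover 90.3% of 15.5 kb at Dlx1 and Dlx2 and 13.6% of 66.25 kb at Dlx5 and Dlx6.

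In FTneg cells far more regions were more open in the KO than in WT: 727 KO-higher against 53 WT-higher, so that 93.2% of 780 regions were KO-higher. KO-higher regions lay mostly away from gene ends (4.68% at one, 3.37 to 6.46), with 45.9% (42.4 to 49.6) inside genes and 178 regions more than 100 kb from any curated protein-coding gene. After 3 positions with extreme summit values, the 2 of highest area lay 219298 bp from Prkd1 (chromosome 12, 50120201 to 50122912, area 4771) and within Ap3b1 (chromosome 13, 94545644 to 94546681, area 2655). The next were nearest to Cited2 (area 2538), over 1 Mb away, and Zfp324 (area 2345). Auts2, a gene of neuronal development, held 2 of the 20 highest (chromosome 5, 131645639 to 131647057 and 131531562 to 131532444, areas 2215 and 2087). Others among the 20 highest were 2722 bp from Sox21, a transcription factor of neural progenitors (chromosome 14, 118229739 to 118231374, area 1949), nearest to Tle1 (area 2168), Samd5 (area 2147), Asb4, Dct, Tmem229a, Pdcd1 and Zeb2 (the last over 1 Mb away), or within Hat1 (area 2139), Fbxl17 and Sgcz. The 3 extreme positions, nearest to Esp38, Col19a1 and Lrrc4c, had summit −log10 p values of 36.8, 155 and 55.8 where no other region of the list exceeded 12.1, and none carried a ChIP peak. Genes with 4 regions were Ctnna2, the axon guidance receptor gene Dcc, Tcf12 and Zfp608, and 17 genes had 3, among them Isl1, Ebf3, Setbp1, Tenm2, Marcks and Tle1. At an area of at least 1000 the counts were 152 and 10.

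Regions more open in the KO were over-represented near 3 of the 11 gene lists. Ventricular zone progenitor genes were nearest to 10 regions, 6.27 times the number their share of the genome gives (one-sided exact binomial test over 724 regions on the autosomes and X, adjusted p = 9.71e-05): Hes1 and Gli3 with 2 each and Gsx1, Gsx2, Nkx2-1, Sox9, Pax6 and Tcf7l2 with 1 each. Notch pathway genes were nearest to 5 (7.77 times, exact binomial test, adjusted p = 0.00471), namely Dll1, Nrarp and Rbpj with 1 each and Hes1, which both lists hold, with 2. GABAergic lineage genes were nearest to 17 (2.60 times, exact binomial test, adjusted p = 0.00469), among them 3 near Isl1, 2 at Sox6 and 1 each near Lhx8, Sp8, Sp9, Zeb2, Maf, Foxp2, Zfhx3, Prox1, Nr2f2, Sox11 and Dlx2. The other lists did not pass this exact test: cortical glutamatergic genes had 2 regions (Eomes and Slc17a6, adjusted p = 0.52), oligodendrocyte and astrocyte genes 1 (Olig1), cholinergic genes 1 (Zic4), endothelial and mural genes 1 (Tek), and NuRD subunit, microglial, cell cycle and housekeeping genes 0 (adjusted p = 1 each). With each gene counted once, 8 progenitor, 14 GABAergic and 4 Notch genes were among the 612 nearest genes, with odds ratios over genes of 19.2, 19.8 and 10.3 (one-sided Fisher's exact test, adjusted p = 1.65e-06, 6.33e-11 and 0.0111), a test that takes no account of the length of genome around a gene. With regions and bins within 100 kb of a gene, GABAergic genes no longer passed (8 of 546 regions, 2.37 times, exact binomial test, adjusted p = 0.14), while the progenitor and Notch lists did (8.92 and 9.0 times, adjusted p = 6.61e-05 and 0.0124). Against merged ChIP regions in place of genome bins, none of the 3 lists passed (ratios 2.12 for progenitor, 2.95 for Notch and 1.5 for GABAergic genes, exact binomial test, adjusted p = 0.227, 0.227 and 0.426, unadjusted 0.0223, 0.0293 and 0.0678).

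The regions less open in KO FTneg cells concentrated at Dlx genes. Of the 53 WT-higher regions 16 were nearest to a GABAergic lineage gene (33.4 times, exact binomial test, adjusted p = 9.31e-19): 9 near Dlx6, 3 near Dlx2, 2 near Dlx1, 1 near Slc32a1, which encodes the vesicular GABA transporter (chromosome 2, 158605262 to 158606426, area 921), and 1 near Sox11. Without the regions at the targeted locus 11 of 48 remained (25.4 times, exact binomial test, adjusted p = 2.38e-11). These 11 include the 9 near Dlx6. The test counts neighbouring regions as independent, so both results rest largely on the Dlx loci and not on the gene list as a whole. The 9 regions near Dlx6 lay from 6806196 to 6872445 on chromosome 6, the one of highest area within the gene (6865643 to 6867732, area 1516). Outside the Dlx loci the regions of highest area lay 145308 bp from Kcnn2, a potassium channel gene (chromosome 18, 45122904 to 45123930, area 1932), and within Zdhhc13 (chromosome 7, 48803339 to 48803937, area 1079). None of the other 10 gene lists had a region.

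In FTpos cells, from the ventricular zone, the calls were few and ran the other way, with 12 KO-higher and 33 WT-higher regions. Of the 12 KO-higher regions 11 overlapped a KO-higher FTneg region, among them those near Esp38, Col19a1 and Lrrc4c. Others lay at the adjoining histone genes H2bc7 and H2ac7, at Pgk1, a glycolytic gene (chromosome X, 106186762 to 106187257, area 827), within the agouti gene a and Cobl, near Zfp324 and Lnx1, and at 2 places near Dlx2 (chromosome 2, 71576890 to 71579949 and 71636474 to 71636876). Of the 33 WT-higher regions 8 overlapped a WT-higher FTneg region, and 7 were nearest to GABAergic genes (23.5 times, exact binomial test, adjusted p = 3.74e-07): 3 near Dlx1, 2 near Dlx2, 1 near Dlx6 and 1 near Sox11. After removal of the Dlx1 and Dlx2 locus and of positions with extreme summit values, 2 of 25 were (8.86 times, exact binomial test, adjusted p = 0.188). The KO-higher list had 2 regions near Dlx2 (18.5 times, exact binomial test, adjusted p = 0.0372 over 44 tests, not passing over the 11 tests of that list alone), of which 1 lay within 50 kb of the gene. This call was lost without the technical regions (1 of 8 regions), against merged ChIP regions and with each gene counted once (exact tests, adjusted p = 0.44, 0.214 and 0.124). The WT-higher list also had 1 region near the endothelial gene Pecam1 (28.2 times, exact binomial test, adjusted p = 0.219), and the remaining lists had none. Other WT-higher FTpos regions of high area lay at Cwc22 (chromosome 2, 77945894 to 77946518, area 1664) and within Pola1 and Abracl.

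KO-higher calls made up 93.2% of 780 regions in FTneg and 26.7% of 45 in FTpos (odds ratio 37.7, Fisher's exact p = 7.92e-26). The sample titles give the same embryo numbers for both fractions, which this test does not take into account. At an area of at least 1000 FTpos had 6 KO-higher and 8 WT-higher regions, and the odds ratio was 20.3. Those 8 were regions at Dlx1 and Dlx2, near Col19a1, at Cwc22 and within Pola1. With technical regions left out FTpos had 8 KO-higher and 25 WT-higher regions (odds ratio 47.1). At 2 positions, near Col19a1 and Esp38, FTpos cells had overlapping regions in both the KO-higher and the WT-higher list.

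Most regions that were more open without DLX1 and DLX2 carried NuRD. Of the 727 KO-higher FTneg regions 518 (71.3%, 67.9 to 74.4) overlapped a peak of at least 1 subunit, 30.7 times the 2.32% after shifts (adjusted permutation p = 0.00144). RBBP4 was at 66.0% of them, RBBP7 at 43.3%, the CHD4-labelled list at 39.2%, MBD3 at 36.2%, the HDAC2-labelled list at 25.9% and the HDAC1-labelled list at 22.4%. A merged ChIP region of 3 or more lists overlapped 43.5% of them, and one of all 6 lists overlapped 109 (15%, 12.6 to 17.8, against 0.170% after shifts). The 109 included regions near Prkd1 and Sox21 and within Auts2, Gli3 and Hat1. Hat1 lies close to the targeted locus (region at 71418686 to 71419409 on chromosome 2, with Dlx1 from 71528113). In the counts of 3 or more and of all 6 lists, the peaks of every list need not overlap the accessibility region itself.

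The share of regions with a NuRD peak was not found to differ between those more and less open in the KO: 38 of 53 WT-higher FTneg regions had one (71.7%, 58.4 to 82.0, odds ratio 0.978 for KO-higher over WT-higher, Fisher's exact p = 1). That call changed when the RBBP4 list was left out (59.0% against 43.4%, odds ratio 1.88, Fisher's exact p = 0.0305), and at an area of at least 1000 the odds ratio was 0.142 (75.0% of 152 against 10 of 10 regions, Fisher's exact p = 0.119). Of the 6 ChIP lists taken singly, RBBP7 alone, from 1 library, differed in share between KO-higher and WT-higher regions. RBBP7 was at 43.3% of KO-higher and 5.66% of WT-higher regions (odds ratio 12.7, Fisher's exact test, adjusted p = 6.11e-08). A merged ChIP region of all 6 lists overlapped 15% and 1.89% (odds ratio 9.17, Fisher's exact test, adjusted p = 0.00850). Such a region always holds an RBBP7 peak, so this contrast is not separate from that of RBBP7. By the same exact test MBD3 (36.2% and 22.6%, adjusted p = 0.0947), RBBP4 (66.0% and 71.7%, adjusted p = 0.564) and 3 or more lists (43.5% and 30.2%, adjusted p = 0.102) did not pass, nor did the CHD4-labelled, HDAC1-labelled and HDAC2-labelled lists (adjusted p = 0.564, 0.916 and 0.453). With the targeted locus and extreme positions left out, RBBP7 was at 43.6% of 723 and 2.08% of 48 regions. At an area of at least 1000 it was at 46.1% of 152 and 30.0% of 10 (Fisher's exact p = 0.514), and a merged ChIP region of all 6 lists overlapped 19.1% and 10.0% (Fisher's exact p = 0.69).

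**Figure D4:**
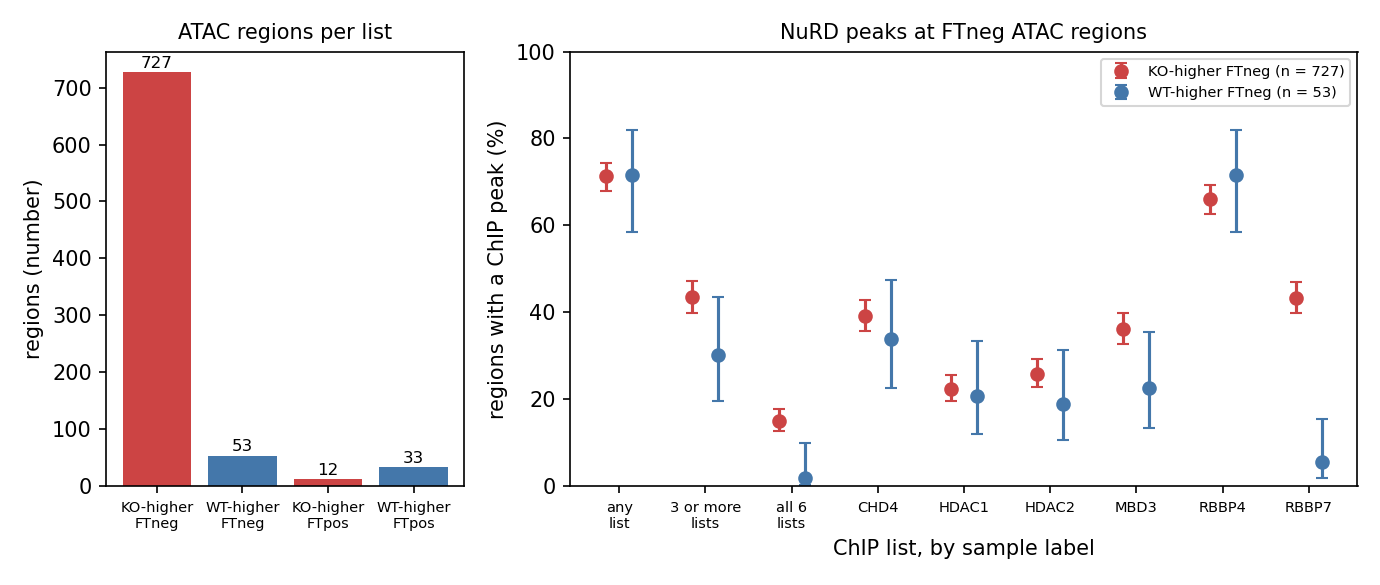
Number of regions in each of the 4 accessibility lists (left, bars) and share of FTneg regions (%) that overlap a ChIP peak (right, points with Wilson 95% intervals) for KO-higher regions in red and WT-higher regions in blue, by ChIP list as labelled. The share with any list is 71.3% and 71.7%, while RBBP7 is at 43.3% of KO-higher and 5.66% of WT-higher regions.

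In FTpos cells, 1 of 12 KO-higher and 29 of 33 WT-higher regions carried a NuRD peak (odds ratio 0.0125, Fisher's exact test, adjusted p = 8.64e-06). RBBP4 was at 87.9% of the WT-higher regions, the CHD4-labelled list at 72.7% and MBD3 at 63.6%. The KO-higher list includes the extreme positions near Esp38, Col19a1 and Lrrc4c, and blacklisted regions had been removed from the ChIP lists. Without the targeted locus and extreme positions the counts were 1 of 8 and 23 of 25 (Fisher's exact p = 6.29e-05). The 8 still include the regions at Pgk1, at H2bc7 and H2ac7 and within the agouti gene, so the contrast rests on few and particular KO-higher regions.

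Seen from the ChIP side, merged regions of more lists more often overlapped a region called more open in the KO. Away from gene ends, the share of merged regions that overlapped a KO-higher FTneg region was 0.758% with 1 list, 1.66% with 2, 2.98% with 3, 4.30% with 4, 5.45% with 5 and 11.0% (9.09 to 13.2) with 6. The odds ratio of 6 lists over 1 was 16.1 (Fisher's exact p = 4.01e-66). This comparison was chosen after the data were seen. Shares by number of lists are not given here for WT-higher or for all open regions, so whether the rise is particular to KO-higher calls was not tested. Regions of more lists were wider (median 1540 bp with 6 and 397 bp with 1). Among regions of 800 to 2000 bp the shares were 11.8% of 671 and 0.499% of 801.

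Gene ends held 4.68% of KO-higher and 15.1% of WT-higher FTneg regions (odds ratio 0.276, Fisher's exact p = 0.00517). Of the 8 WT-higher regions at gene ends 5 lay at Dlx1 and Dlx2, and with that locus and the extreme positions left out the odds ratio was 0.74 (Fisher's exact p = 0.496). A gene end window of 500 bp gave 0.454 (Fisher's exact p = 0.14). In FTpos the shares were 25.0% of 12 and 15.2% of 33 regions (Fisher's exact p = 0.661).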

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

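The tests on the counts, on the targeted locus and on the positions called both ways were chosen after the results were seen. The direction of the KO calls differed between the fractions, with an odds ratio of 37.7 for KO-higher calls in FTneg over FTpos, by Fisher's exact test on the lists.

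Technical explanations of the excess of KO-higher regions in FTneg cells (727 against 53) could be tested only in part. A uniform difference in scaling would raise strong constitutive sites too. At gene ends lay 4.68% of KO-higher regions, against 33.7% of all merged ChIP regions. Merged ChIP regions are not a list of all open regions, which was not available here, so this comparison cannot decide on scaling. Sequence linked to the targeted locus would put most KO-higher regions on chromosome 2, which held 8.53%, so it cannot account for most of the excess. X and Y held 2.48%, so calls on the sex chromosomes do not make up the excess either. On Y lay 3 KO-higher and 0 WT-higher FTneg regions, so a different sex of the embryos in the 2 genotypes is not excluded. What stays open is a difference in scaling, depth, library quality, sex or cell composition between the genotypes, which the lists cannot settle. The change of genotype itself stays open too. With the embryos combined in each list and no value per embryo, the spread between embryos is unknown.

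The WT-higher regions at Dlx1 and Dlx2 may reflect the missing DNA of the targeted deletion and not a change of chromatin. They covered 90.3% of the stretch between the first and the last of them, intervals between open sites included, against 13.6% at Dlx5 and Dlx6. The deletion's own coordinates were not used here, and no biological explanation was tested for this stretch.

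In FTpos cells the positions near Col19a1 and Esp38 were called in both directions. Their median area was 18.5 times that of the regions of the 4 lists together, and none carried a ChIP peak, in lists from which blacklisted regions had been removed. Within each list, the KO-higher calls had 33.0 and 16.5 times the median area of their list and the WT-higher calls 0.895 times near Esp38 and 12.1 times near Col19a1, so the WT-higher call near Esp38 did not stand out. Reads from sequence present in many copies are a candidate explanation for these positions, and no biological one was tested. A further position, at Cwc22, was KO-higher in FTneg and WT-higher in FTpos and did carry a ChIP peak.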

How the results depend on the processing

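Alternatives that left out technical regions, that left out the RBBP4 list from the overlap with accessibility regions, that used all protein-coding genes, and all those on the KO-higher share by number of lists, were chosen after the data were seen. Of 75 alternatives over 17 results, 56 kept the direction and the side of the threshold, or a count within 1.5 times. Both numbers include the alternatives that renamed pairs of ChIP lists. Those reused the same pairs, all of which had passed, so their agreement was fixed in advance. The pairwise overlap, the direction of calls between fractions, the share of KO-higher regions with NuRD and the KO-higher share by number of lists did so in every alternative run. For the changes below the cause was not tested, except where fewer peaks or regions entered. Regions of all 6 lists numbered 219 at a −log10 q of at least 10, 247 with lists of equal length and 1001 with summits within 250 bp, and 2706 regions held the other 5 lists without the HDAC2-labelled one. For the gene end share of regions of 6 lists over 1, the first 3 settings gave odds ratios of 0.621, 0.761 and 0.923 in place of 2.51. An area of at least 1000 left 152 KO-higher and 10 WT-higher regions in FTneg and 6 and 8 in FTpos. The odds ratio of NuRD at KO-higher over WT-higher FTneg regions was 1.78 for merged ChIP regions of at least 3 lists, 9.17 for those of all 6 lists, 1.11 away from gene ends, 1.15 without technical regions and 1.88 without the RBBP4 list (Fisher's exact p = 0.0305), in place of 0.978. It was 0.142 at an area of at least 1000 (Fisher's exact p = 0.119) and 0.752 at a −log10 q of at least 10. The gene end share of KO-higher over WT-higher regions no longer passed with a 500 bp window (0.454) or without technical regions (0.74). With merged ChIP regions as background 0 gene lists passed, in place of 3, and within 100 kb of a gene 2 did. Counted once per gene, the GABAergic list had the highest odds ratio of the 3 (19.8). The names the lists carry moved the log2 ratio of CHD4 with MBD3 from 6.0 to 7.05 and of HDAC1 with HDAC2 from 6.64 to 6.4. No paired analysis was possible because the lists combine the embryos and hold no value per embryo, and for the same reason no embryo could be left out. The alternatives of the motif comparison were not run. Depth per library was not known, so short lists may reflect shallow libraries as well as fewer sites, and the 219 regions left by the stricter threshold show how far these counts depend on what is called.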

Other observations

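The tests on Pgk1, on the names of the lists and on progenitor genes were set before their results were seen, and the test on chromosome 2 and the direct comparison of progenitor with GABAergic genes after. RBBP7 had 34.4% and RBBP4 32.5% of their merged regions in no other list, against 2.65% for the HDAC1-labelled list and 4.26% for MBD3. Leaving out RBBP4 added 0 regions to those of all 6 lists, so that every region with the other 5 lists also held RBBP4, while leaving out the HDAC2-labelled list added 1179. The X chromosome held 2.00% of the CHD4-labelled peaks and 0.620% of the HDAC1-labelled ones.

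A hypothesis on the 3 lists whose names differ from their samples is that lists which share an input are more alike. Paired by the names they carry, lists sharing an input had a mean log2 overlap ratio of 6.32, the highest of the 15 ways of pairing 6 lists. Paired by the sample labels it was 6.05, which had rank 6. The carried names may thus be the right ones, but the chance of ranking first is 1 in 15 and the ratio also depends on list length.

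The KO-higher region at the end of Pgk1 may come from a selection cassette with the Pgk1 promoter in the knockout, which would be present in every cell. Such a region was also KO-higher in FTneg cells (1 region at Pgk1, area 951, chromosome X, 106186695 to 106187271). Of the 12 KO-higher FTpos regions 11 overlapped a KO-higher FTneg region, so this recurrence does not favour a cassette. Whether the allele holds a cassette was not given in the sources used here, and a change at Pgk1 itself stays open.

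Regions on chromosome 2 lay near the targeted locus more often than its bases do. Within 20 Mb of Dlx1 and Dlx2, but more than 50 kb away, lay 27 of 74 regions over the 4 lists, 1.63 times the share of bases (exact binomial p = 0.00401), while merged ChIP regions had 0.881 times that share. DNA of another strain carried along with the targeted allele may contribute, as may effects of the deletion on its neighbours, and the lists overlap in part, so that p is too small. KO-higher regions far from the locus, on other chromosomes, are not covered by this.

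A hypothesis on the ventricular zone progenitor genes is that regions open in progenitors were kept open without DLX1 and DLX2. These genes were over-represented near KO-higher FTneg regions 6.27 times against genome bins, and GABAergic lineage genes 2.60 times. Of the 27 regions near either list 37.0% were near progenitor genes where the bins give 19.6% (two-sided exact binomial p = 0.0295), which rests on the same regions and bins as the ratios, while with each gene counted once the odds ratios over genes were 19.2 and 19.8. Against merged ChIP regions the ratios over regions were 2.12 and 1.5 and neither list passed (exact binomial test, adjusted p = 0.227 and 0.426). The over-representation may thus be shared with regions that hold a NuRD subunit peak in general. Accessibility in WT progenitors at these regions was not measured in the lists, and a higher share of progenitors in the FTneg fraction of the KO would give the same pattern.

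The KO-higher region near Dlx2 in FTneg cells (chromosome 2, 71578904 to 71580023) and the one that overlaps it in FTpos cells carried no ChIP peak. The region in the agouti gene a was KO-higher in both fractions (areas 1000.01 and 1327). Of the KO-higher FTneg regions 15 lay on X and 3 on Y.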
